A study of Oryza sativa with 6 samples.

How the data were processed

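RNA was sequenced from developing rice seeds, collected 10 to 14 days after flowering and dehulled, from plants kept in growth chambers with 12 h of light and 12 h of darkness at 27 °C, per the labels. The 6 libraries were 3 of the wild-type cultivar ZH11 and 3 of rbpl, a line in which RBP-L is knocked down; the design text calls the 3 of each group biological repeats. Total RNA was made into libraries with the NEBNext Ultra RNA kit and sequenced by a company, per the labels' protocols. The aligner, the read counter, the genome build and the gene annotation are not given in the sources used here.

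The authors deposited 1 table of 55986 loci with the RPKM (reads scaled to the length of the gene model and to the depth of the library) of each of the 6 libraries, per the file headers. Of the loci, 55801 have identifiers of the LOC_Os form, which carry the chromosome number, and 185 lie on unplaced sequence. The same table holds the authors' group means in RPKM, the ratio of the means, its log2 fold change, a p-value and its −log10, per the file headers. The deposited p-value equals an equal-variance test of the untransformed RPKM within a tolerance of 1e-06 in 100% of loci with a number there, and it is not adjusted for the number of loci. These columns were used only to set the authors' calls beside those made here.

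The file gives no read counts, but a locus's RPKM values are whole multiples of what 1 read is worth at its length and depth. Library totals and whole reads were recovered from these steps. Of 32287 loci with a value above 0 in at least 1 library, 99.997% gave whole reads in all 6 within a tolerance of 0.001 reads. A divisor shared by all 6 counts of a locus cannot be seen, so some low counts are too small by that factor. On 5762 simulated loci the method returned 98.6% of counts exactly and 99.3% up to such a divisor. The recovered totals lie between 44187374 and 50714582 reads per library, of which the loci hold between 93.0% and 94.0%. Recovered reads served for depth, for the reads of single loci, for loci without reads and for 1 alternative test. They also served for the chi-square tests of replicates and for the read minimum and summed reads of the runs of neighbours. Read-based limits cover counting error only; no molecular identifiers are mentioned in the labels.

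The main test was limma 3.58.1 (R 4.3.3, trend and robust options, no covariates) on log2(RPKM + 1), on the 17507 loci with a mean RPKM of at least 1 in at least 1 group, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change on this scale is the knockdown minus the wild type and understates the change of low loci. Read-count tests had been planned before the data were examined, with these settings as the fallback for a file of normalised values, and the fallback was used because the file holds RPKM. On data simulated from the comparison of rbpl with the wild type over 17507 loci, the test recovered 72% of 100 loci changed 2-fold and 94% of 100 changed 4-fold, and called 11 unchanged loci. The simulated changes were not placed on the lowest loci. Errors were drawn independently with the same spread in both groups, so a library that departs at many loci at once was not represented. Single values were compared by exact permutation tests, two-sided, which with 3 against 3 libraries cannot give a p below 0.1. Counts per chromosome were compared by Fisher's exact test with Benjamini-Hochberg adjustment over the 12 chromosomes.

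Runs of changed neighbours were sought by counting the loci that rose, or fell, in windows of 20 tested loci in order of locus number, against 1000 random orders. Median ratios over a run were taken over its loci with a mean of at least 20 reads per library, called or not, with 95% bootstrap intervals from 2000 draws. Both steps were chosen after the data were seen. The intervals treat neighbouring loci as independent and give the spread over loci within a library, not that between libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps, and matplotlib 3.10.9 for the plots.

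None of the identifiers of the file was found in the reference table of 39387 rice genes (0 matched), and the files do not pair the identifiers with names. The 38 gene lists fixed before the data were examined hold 91 locus identifiers of another form, of which 0 were found in the file. The lists, which cover among others seed storage proteins and starch synthesis, were therefore not tested. The rule for named genes took RBP-L first, then the 10 largest changes in each direction among loci with an adjusted p below 0.05, a level above the median of the tested loci, non-overlapping groups and an informative description. With no descriptions, 537 loci met the other conditions (290 that rose, 247 that fell). Only 2 identifiers that rose and 2 that fell are printed, and 1 of the latter is RBP-L. It is there as the target and not for the size of its fall (log2 fold change −1.86). The second-largest fall by the rule, a log2 fold change of −3.11 at a locus of chromosome 12, is not named. RBP-L was taken, from background knowledge and before the data were examined, to be the locus LOC_Os04g53440; the files themselves do not state this.

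Alternatives were other pseudocounts (0.1 and 0.5), no filter and a filter at 5 RPKM, the replicate number as a block, each library left out in turn and, added after seeing the data, 2 other scalings, limma-voom on the recovered reads and a test without the starts of chromosomes 11 and 12. Replicate libraries were compared by chi-square tests of their recovered reads. The chi-square per degree of freedom was between 12.9 and 137 within groups, so no pair looked like 1 library deposited under both names. This says nothing of whether the repeats are biological, which rests on the design text.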

Results

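Gene expression in developing rice seeds was measured by RNA sequencing in the wild-type cultivar ZH11, a japonica rice, and in the rbpl line, in which the RNA-binding protein RBP-L is knocked down. Each group held 3 biological repeats, named here WT-1 to WT-3 and rbpl-1 to rbpl-3, and nothing in the labels pairs them across groups. The totals recovered from the deposited RPKM values were 47072581, 44187374 and 50714582 reads for the wild type and 47633680, 50159592 and 48406895 for the knockdown. Between 16748 and 17188 loci per library had at least 1 RPKM. The question of the design is which transcripts change in the grain when RBP-L is lowered. Because a single rbpl line was set against the cultivar, an effect of RBP-L cannot be told apart from the descent of the line. This holds for all changed loci below.

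RBP-L transcript (LOC_Os04g53440, chromosome 4, a gene model of 1725 bp by the recovered reads) was lower in each knockdown library than in each wild-type library. Its level was 62.8, 56.8 and 51.2 RPKM in the wild type and 15.1, 14.4 and 15.3 RPKM in the knockdown, from 5098, 4328 and 4479 reads against 1240, 1244 and 1277 reads. The group means were 56.9 ± 5.79 RPKM (SD, n = 3) and 14.9 ± 0.481 RPKM (SD, n = 3), a level 3.81-fold lower that left 26.2% of the wild-type transcript. The log2 fold change was −1.86 with a standard error of 0.11 and an adjusted p of 0.000159 by limma. The exact permutation test of the RPKM values gave p = 0.1, the smallest it allows. In the authors' deposited table the log2 fold change is −1.93 with an unadjusted p of 0.000235. Of the 20 nearest tested loci, 10 on each side, 0 changed by limma (5 had an unadjusted p below 0.05, and limma-voom called 0), with log2 fold changes from −0.55 to 0.41. Over all 17507 tested loci 6.56% changed and 3777 had an unadjusted p below 0.05 by limma, so 0 of 20 does not set these neighbours apart. Without WT-1, 1 of these neighbours rose and 1 fell.

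**Figure D1:**
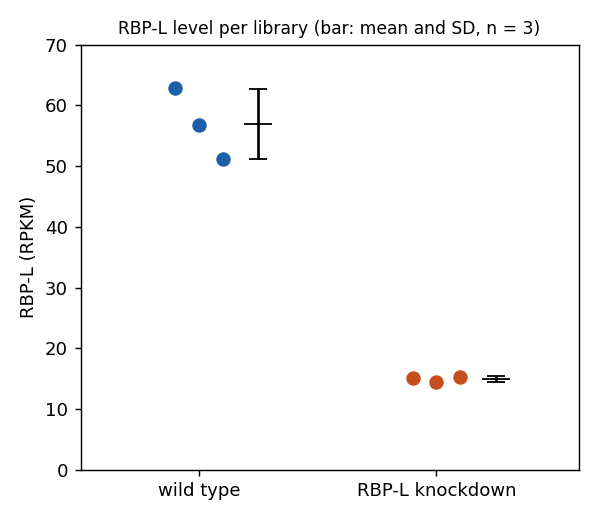
RBP-L level (RPKM, linear axis from 0) in each of the 3 wild-type and 3 knockdown libraries; points are libraries and the bar gives the mean and SD of each group. The knockdown libraries lie between 14.4 and 15.3 RPKM and the wild-type libraries between 51.2 and 62.8 RPKM.

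Across the transcriptome, 605 loci rose and 543 fell in the knockdown, together 1148 of 17507 tested loci (6.56%; limma, adjusted p below 0.05). A change of at least 2-fold was found for 343 of them, 199 that rose and 144 that fell, and at least 4-fold for 47 that rose and 16 that fell. Without the starts of chromosomes 11 and 12, 145 rose and 132 fell at least 2-fold. The 4-fold counts were not repeated without these starts. They include the run of rises on chromosome 11 described below, where the upper quartile of the log2 fold change was 3.00. By limma-voom on the recovered reads 312 rose and 275 fell at least 2-fold. A pseudocount of 0.1 was the only alternative that turned this excess of rises into one of falls, with 264 that rose and 278 that fell. Among loci with a level above the median of the tested loci, LOC_Os03g02470 on chromosome 3 had the largest rise, from 0.0767 ± 0.00527 RPKM (SD, n = 3), 6 reads in each wild-type library, to 108 ± 3.09 RPKM (SD, n = 3), a log2 fold change of 6.66 with an adjusted p of 3.23e-08 by limma. Its fold depends on how low values are treated, with a log2 fold change of 10.34 by limma-voom on the recovered reads and 9.25 with a pseudocount of 0.1. LOC_Os01g35330 on chromosome 1 rose from 1.04 ± 0.447 to 133 ± 15.8 RPKM (SD, n = 3 each), with a log2 fold change of 6.05 and an adjusted p of 3.0e-06 by limma. The largest fall was that of LOC_Os09g25060 on chromosome 9, from 45.7 ± 0.731 to 1.30 ± 0.0507 RPKM (SD, n = 3 each), with a log2 fold change of −4.35 and an adjusted p of 4.55e-07 by limma. What these 3 loci encode is not paired with the identifiers in the files.

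By abundance, 356 loci rose and 347 fell among the 10476 tested loci with a mean below 10 RPKM. Between 10 and 100 RPKM, 197 rose and 176 fell of 6062. Between 100 and 1000 RPKM, 51 rose and 19 fell of 903, and of the 66 loci at or above 1000 RPKM, 1 rose and 1 fell. Of the 20 loci with the highest mean RPKM, between 2055 and 15726 RPKM, 0 changed by limma (smallest adjusted p 0.0671; 5 had an unadjusted p below 0.05, and limma-voom called 0). Their fitted log2 fold changes ran from −0.85 to 0.50. Since 6.56% of all 17507 tested loci changed and 3777 had an unadjusted p below 0.05 by limma, 0 of 20 does not set these loci apart. Together these 20 loci held 16.9 ± 1.45% (SD, n = 3) of the summed RPKM in the wild type and 15.6 ± 0.476% (SD, n = 3) in the knockdown, a difference that did not exceed the spread between libraries (exact permutation p = 0.3; smallest possible 0.1). WT-1 had the highest share, 18.5%, and without WT-1, 2 of the 20 loci fell.

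WT-1 stood apart from the other libraries. Over the tested loci, which are not independent replicates, its log2 values correlated with those of WT-2 and WT-3 at r = 0.965 and 0.966, against 0.995 between WT-2 and WT-3 and 0.993 to 0.994 among the knockdown libraries. WT-2 and WT-3 correlated more with each knockdown library (0.970 to 0.974) than with WT-1, and WT-1 with the knockdown libraries at 0.953 to 0.963. In WT-1, 576 tested loci lay at least 2-fold from both other libraries of its group, 149 higher and 427 lower, while each other library had between 3 and 14 such loci. The first principal component, with 53.0% of the variance, separated the groups, and the second, with 33.9%, placed WT-1 at 36.8 and WT-2 and WT-3 at −24.3 and −23.4. Leaving out WT-1 raised the count of changed loci to 3130, of which 1142 were among the 1148, and turned the excess of rises into one of falls (1478 rose, 1652 fell). Leaving out another library lowered it, to 736 without WT-2, 667 without WT-3, 356 without rbpl-1, 389 without rbpl-2 and 453 without rbpl-3, and without rbpl-1 the loci changed at least 2-fold numbered 215. By abundance, without WT-1, 754 rose and 917 fell below 10 RPKM, 558 rose and 632 fell between 10 and 100 RPKM, 157 rose and 96 fell between 100 and 1000 RPKM, and 9 rose and 7 fell of 69 loci at or above 1000 RPKM. Those changed at least 4-fold without WT-1 were 77 that rose and 11 that fell. These counts include the start of chromosome 11, where 75 loci were called without WT-1, and were not repeated without it.

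**Figure D2:**
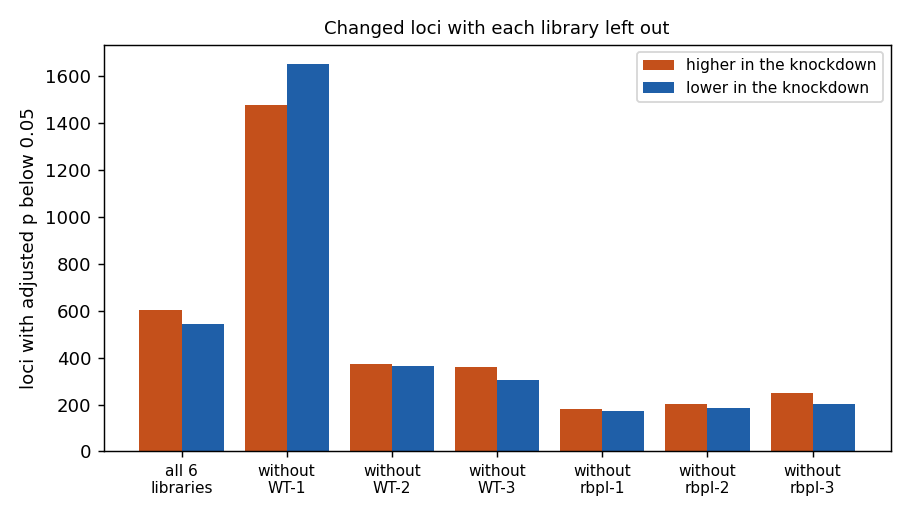
Number of loci with an adjusted p below 0.05 by limma (linear axis from 0), higher or lower in the knockdown, with all 6 libraries and with each library left out. The total is 1148 with all libraries, 3130 without WT-1 and between 356 and 736 when another library is left out.

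Changed loci were concentrated at the start of chromosomes 11 and 12, in order of locus number. On chromosome 11, 101 of 811 tested loci changed (12.5%; 73 rose and 28 fell), and on chromosome 12, 113 of 948 (11.9%; 26 rose and 87 fell), each with an adjusted p of 2.2e-09 by Fisher's exact test. The other chromosomes had 5.47% to 7.19% changed loci, with adjusted p of at least 0.142. A run from the tested locus 6 to 80 of chromosome 11 held 75 tested loci, of which 57 rose and 0 fell, with a median log2 fold change of 1.94. A run from the tested locus 4 to 110 of chromosome 12 held 107 tested loci, of which 67 fell and 1 rose, with a median log2 fold change of −0.70. Windows of 20 tested loci held up to 18 loci that rose in the first run and up to 16 that fell in the second, against at most 8 in 1000 random orders. Fisher's exact test and the random orders both treat loci as independent, which neighbours need not be. Neither therefore tells how many separate changes there were. Relative to the knockdown mean, the median level of the chromosome 11 loci was 0.413 (95% interval 0.373 to 0.454, 90 loci) in WT-1, 0.00275 in WT-2 and 0.00388 in WT-3. At the chromosome 12 loci the median was 1.81 (1.57 to 1.93, 120 loci) in WT-1, 1.97 (1.80 to 2.08) in WT-2 and 2.07 (1.93 to 2.13) in WT-3. All other tested loci had medians of 1.09, 1.02 and 1.02 in these libraries. Among loci of these regions too low for the test, with a mean of at least 0.1 RPKM, 35 of 36 on chromosome 11 were higher in the knockdown and 19 of 21 on chromosome 12 were lower.

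**Figure D3:**
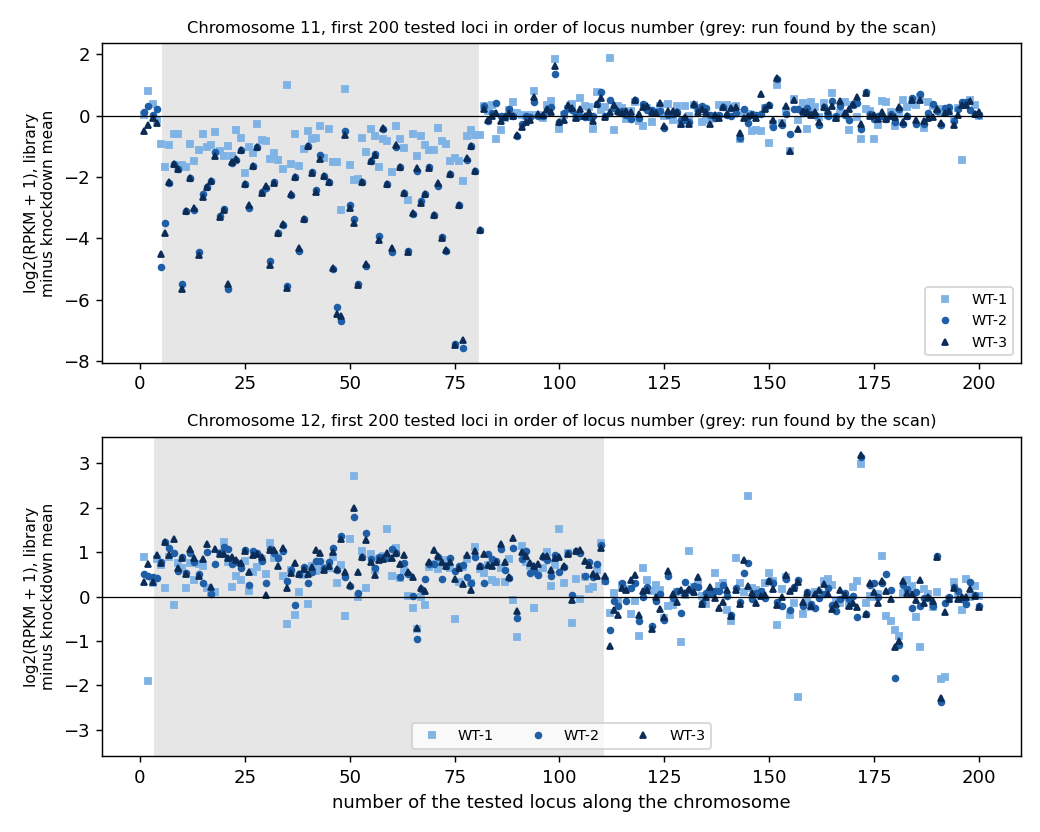
Each wild-type library's log2(RPKM + 1) minus the knockdown mean, for the first 200 tested loci of chromosomes 11 and 12 in order of locus number; points are loci and the grey area is the run found by the window scan. In the grey area WT-2 and WT-3 lie below 0 at nearly all chromosome 11 loci with WT-1 between them and 0 at most loci, and all 3 libraries lie mostly above 0 at the chromosome 12 loci.

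Together the runs on chromosomes 11 and 12 held 125 of the 1148 changed loci (10.9%). Outside them 547 loci rose and 476 fell, 1023 in all, and among these no chromosome stood out (adjusted p of 1 for each by Fisher's exact test). The runs were picked for their calls, so that chromosomes 11 and 12 no longer stood out is in part built in. After adjustment over the remaining loci alone, 958 changed. The starts of these chromosomes are known to share a large duplicated block in rice, and reads of near-identical copies could be given to either, so the levels of single loci there are uncertain. The calls in the chromosome 11 run were 75 without WT-1 but 24 without WT-2, 25 without WT-3, and 13, 17 and 15 without rbpl-1, rbpl-2 and rbpl-3; in the chromosome 12 run they were 43 without WT-3 and 29, 32 and 40 without rbpl-1, rbpl-2 and rbpl-3.

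A shorter run lay on chromosome 5, from the tested locus 559 to 571 of 1526. Of its 13 tested loci 10 rose and 0 fell, with log2 fold changes of 0.51 to 2.42 for those that rose and a median of 1.16 over all 13. Summed over the 13 loci the level was 1203 ± 155 RPKM (SD, n = 3) in the wild type and 2881 ± 491 RPKM (SD, n = 3) in the knockdown; the loci were chosen by the scan for their calls, so these sums describe the run and do not test it. The sums were 1247, 1331 and 1030 RPKM in WT-1 to WT-3 and 2754, 2466 and 3423 RPKM in rbpl-1 to rbpl-3. A window there held 10 loci that rose, against at most 8 in random orders. Random orders treat neighbours as independent, so neighbours that share reads or change together can exceed them without 10 separate changes. Without WT-1 the run again held 10 calls, but at loci already picked for their calls. Whether these neighbours are copies of one another, which would let them share reads, was not analysed here.

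In the authors' deposited table, 4422 loci have an unadjusted p below 0.05, of which 1909 have a log2 fold change above 0, 2355 below 0 and 158 no number, since the wild-type mean (88 loci) or the knockdown mean (70 loci) is 0. The limma calls made here were 605 that rose and 543 that fell. These counts are not alike: the deposited p is unadjusted, from untransformed RPKM, and covers 32287 loci. The limma p is adjusted, from the log scale, and covers the 17507 loci past the filter. Of the 4422, 667 are at least 2-fold higher and 655 at least 2-fold lower in the knockdown. Of the 1148 loci called here by limma, 1118 (97.4%) have a deposited p below 0.05. Both tests used the same libraries and the deposited p is not adjusted, so this overlap is no separate evidence.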

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

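The other scalings, limma-voom on the recovered reads and the test without the starts of chromosomes 11 and 12 were chosen after seeing the data; the other alternatives were planned. RBP-L was lower in the knockdown in all 15 alternatives, with log2 fold changes from −1.93 to −1.79 and adjusted p from 1.22e-07 to 0.00402 by limma. The named loci on chromosomes 1, 3 and 9 also kept their direction and stayed past the threshold in all 15, with log2 fold changes from 5.86 to 7.06, 6.63 to 10.34 and −5.13 to −4.30. The run on chromosome 5 held 8 to 10 calls in all of them. Leaving out 1 library gave 356 to 3130 changed loci (3130 without WT-1, 356 without rbpl-1), 215 to 397 changed at least 2-fold, 13 to 75 calls in the chromosome 11 run and 29 to 91 in the chromosome 12 run; with fewer libraries the counts fell, except without WT-1. With the filter at 5 RPKM, which tests fewer loci (10744), 660 loci changed and 223 changed at least 2-fold, with 21 calls in the chromosome 11 run and 39 in the chromosome 12 run. A pseudocount of 0.1 gave 542 loci changed at least 2-fold, and limma-voom, which differs in several choices at once, 587. The chromosome 11 run held 21 calls with the pseudocount of 0.1 and 32 with no filter. The cause was not tested for any of these. Median-of-ratios scaling put 60.1% of the calls among those that rose, against 52.7%.

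The replicate numbers are only shared: the deviations from the group means correlated at 0.0476, 0.259 and −0.380 between same-numbered samples, and 2 of 6 libraries correlated best with their own number. With the replicate number as a block 963 loci changed, 863 of them among the 1148. Of the settings foreseen for a file of read counts, trimmed-mean normalization and the negative-binomial tests were not run, since the deposited unit is RPKM. Median-of-ratios (relative log expression) and upper-quartile factors were applied to the RPKM, giving 1128 and 1162 changed loci, and limma-voom to the recovered reads, giving 1173. The list tests were not run, because no list identifier matched. Depth limits what is seen of a locus without reads: 3 reads over the wild-type group correspond to 0.0211 RPM.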

Other observations

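All tests in this part were chosen after the result was seen. Those for the sum of the chromosome 11 and 12 levels and for the chromosome 12 level of WT-1 were also reworded after their first values were known: the undivided sum was 2.22 in WT-1, against an expected 2 and an allowed difference of 0.5, and the chromosome 12 level of WT-1 was 1.81 (1.57 to 1.93) against an expected 1.59. The interval of the latter overlapped that of WT-2. The test of depth first counted pairs of libraries, of which 3 of 9, all with WT-3, had more reads in the wild type, and was replaced because such pairs do not give the size of the gap.

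Some loci had reads in the knockdown alone. At 21 loci each knockdown library held at least 10 reads and the wild-type libraries 0, and 0 loci showed the opposite. This count was made at a minimum of 10 reads only; among loci with a p below 0.05 in the authors' deposited table, whatever their reads, 88 have a wild-type mean of 0 and 70 a knockdown mean of 0. Of the 21, 1 lay in the chromosome 11 run and 20 elsewhere, on 10 chromosomes in all, with knockdown means from 0.143 to 21.6 RPKM and a median of 0.422 RPKM. With WT-1 left out, 68 loci had reads in the knockdown alone and 31 of them lay outside the start of chromosome 11.

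The grouping itself was set against the other ways to split the 6 libraries into 3 and 3. There are 10 splits, too few for a share under 0.05. Only the real one, 1 of the 10 splits, gave 1148 changed loci, and the highest other gave 1; for loci changed at least 2-fold the values were 343 and 1. For loci with reads in 1 group only they were 21 and 1. Each other split mixes wild-type and knockdown libraries, so a difference between the real groups widens the spread within the mixed ones. That holds the calls of those splits down, and their counts do not show how many calls would arise without a group difference.

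At the start of chromosomes 11 and 12, the wild-type level was close to 0 at the former in WT-2 and WT-3 and near 2 times the knockdown level at the latter. Loss of the chromosome 11 start alone would leave the chromosome 12 loci at 1. The lowest of the 3 wild-type libraries stood at 1.81 there, with an interval from 1.57 that treats neighbouring loci as independent. The run was picked by the scan for loci that fell, so a level above 1 is in part how it was chosen. Its loci too low for the test took no part in that choice, and 19 of 21 were lower in the knockdown. Within these limits the levels argue against loss of the chromosome 11 start alone. Chromosome 12 sequence in place of the chromosome 11 start in the wild-type plants predicts that both levels, each divided by that of all other tested loci, sum to 2; the sums were 2.04, 1.95 and 2.04, the farthest being 1.95, but the hypothesis was drawn from these levels, so the sums are no separate test of it and it stays open. Reads given to the other copy of a near-identical locus cannot be told apart from this replacement by the summed reads. Both keep the sum over the regions equal (wild type over knockdown 0.950), and the file holds no sequence. If all libraries were aligned alike, which is not stated, such reads alone would be shared alike in each. They would then not give chromosome 11 levels of 0.413 in WT-1, 0.00275 in WT-2 and 0.00388 in WT-3. Whether the difference belongs to RBP-L knockdown or to the descent of the sampled lines stays open and untested.

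WT-1 stood at 41.3% of the knockdown level at the chromosome 11 loci, between the other libraries of its group and the knockdown. The 95% interval, 37.3% to 45.4%, treats neighbouring loci as independent and covers the spread over loci of this library only. RNA of the knockdown line in WT-1 would bring to the same share other loci with no read in WT-2 and WT-3 and at least 50 in each knockdown library, but over the 9 such loci outside these regions the median share in WT-1 was 0% with an upper bound of 2.29% (5 had no read in WT-1, and the highest share was 29.0%), which argues against it. A lower RBP-L level in WT-1 is argued against by its RBP-L level, 1.11 times the higher of WT-2 and WT-3. A mixture of seeds with and without the chromosome 11 start predicts a chromosome 12 level in WT-1 of 0.810 of the mean of WT-2 and WT-3, and the value was 0.802 (0.751 to 0.862), but this restates the WT-1 sum above and assumes the replacement, so it gives no separate evidence and the mixture stays open. The 517 loci elsewhere at which WT-1 lay at least 2-fold from both others are not covered by these tests, and a difference in seed age within the 10 to 14 days of sampling stays untested.

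For the loci with reads in the knockdown alone, fewer reads in the wild type is argued against by the small gap in depth. The wild-type libraries together had 2.89% fewer reads, which would leave at least 33.0 reads expected over the group at each of these loci. The 0 reads in the wild type and the minimum of 10 in each knockdown library were the terms on which the loci were picked. Only the depth is therefore evidence here. Whether they reflect RBP-L knockdown or the descent of the line was not tested.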
